A study of Rattus rattus with 6 samples.

How the data were processed

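RNA was taken from the left ventricle of 6 male rats, 3 of 3 months and 3 of 24 months of age, with 1 library per animal per the labels. Per the labels' protocols, total RNA was depleted of ribosomal RNA, and directional paired-end libraries were sequenced on instruments of 2 Illumina models. Which library ran on which model is not given in the sources used here, so no effect of the model could be examined. Per the submitters' processing notes, Salmon was used with the genome build mRatBN7.2. The version, the annotation release and the way transcripts were summed to genes are not given in the sources used here. The labels name the species as Rattus rattus, whereas the Wistar-Kyoto strain and the mRatBN7.2 build belong to Rattus norvegicus.

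The authors deposited a table of TPM (abundances divided by transcript length and brought to a fixed sum) for 23976 genes and 6 libraries, 1 column per library. Each column summed to 1000000. TPM keeps no read depth, and a rise of the most abundant genes lowers the values of all others. No read counts were used here, and no counting interval or detection floor could be given. A value of 0 is reported as listed at 0.

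The 3 young columns carry the individual numbers 2, 4 and 5 of the young samples' labels and were matched to young replicates 1, 2 and 3. Of the numbers in the 3 old columns (OH1, OH2 and OH5), only 5 is among the individual labels of the old samples (5, 11 and 12). The numbers of OH1 and OH2 match no label, and OH5 was not matched on its number alone. All old columns were assigned to the old group and to no single sample, so replicate numbers pair nothing. The column names also end in _1 (young replicates 1 and 3 and OH1) or _2 (young replicate 2, OH2 and OH5). The labels do not explain this suffix; it could mark a batch, and it was left out of the main model. All columns were mapped.

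Gene names could not be attached. The 23976 Ensembl identifiers were looked up in a table of 32100 Rattus rattus RefSeq genes, and 0 matched. Before the data were examined, 36 gene lists had been fixed (19 functional lists and 17 lists of cell type markers and handling genes) with competitive tests of each. None of these lists could be tested. The rule for named genes, also fixed then, asked for a gene symbol. In its place, the 2 genes with the largest rise and the 2 with the largest fall were taken among those past the threshold, with a mean of at least 1 TPM and groups that did not overlap.

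The design had assumed counts and named this test for normalized values: limma-trend (limma 3.58.1 in R 4.3.3) on log2(TPM + 1), with age as the only term, for genes of at least 1 TPM in at least 3 libraries. This left 9502 genes. Adjusted p values are Benjamini-Hochberg values over these genes, with a threshold of 0.05, and fold changes are old over young on the log2(TPM + 1) scale. Beside it, a scaling chosen after the data were seen left out the 15 genes with a mean of at least 1000 TPM and brought the other genes to a sum of 1000000 per library, with the filter unchanged (9487 genes). Groups of 3 libraries were compared on single values with exact two-sided permutation tests, which cannot give less than p = 0.1.

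Both fits were tested on simulated data built from the means and spreads of the 9487 genes. For the fit of the rescaled comparison, 200 genes were changed on log2 values that were already rescaled, so the rescaling step was not tested. The fit recovered 77% of the genes changed by 1 log2 unit and 95% of those changed by 2, with 6 false calls among 178. Noise was drawn separately for each gene, without differences shared by the genes of a library. The part of false calls therefore need not hold for the real libraries. With no gene changed, but with the part of the total outside the 15 genes set to that of each real library, the deposited-scale fit called 271 of 9487 genes, 268 of them lower, a direction set by those shares, and gave an unadjusted p below 0.05 to 5407. After rescaling, the same simulated libraries gave 0 calls by limma and 489 genes with an unadjusted p below 0.05. Rescaling undoes exactly the shares that were set, so this outcome was built in. It does not show that rescaling is right for the real libraries.

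Alternatives fixed before the data were examined were a pseudocount of 0.1, no filter and leaving out each library in turn. Alternatives added later were median-ratio scaling, quantile normalization, a pseudocount of 10, a filter at 10 rescaled TPM, leaving out the 64 genes of at least 100 TPM, leaving out each library after rescaling, and the suffix of the column names as a second term. Tests that need counts, and alternative settings of the list tests, were not run.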

Results

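Left ventricles of male Wistar-Kyoto rats, an inbred strain used as the normotensive control of the spontaneously hypertensive rat, were profiled by RNA sequencing of ribosomal RNA-depleted total RNA. The young adult group was 3 months old and the old adult group 24 months, with 3 libraries in each. The table gave length-normalized transcript abundances (TPM) for 23976 Ensembl rat genes. Every library summed to 1000000 TPM, so neither the read depth nor a counting interval could be derived, and only relative levels could be compared. The table pairs no identifier with a gene symbol, and 0 of the 23976 identifiers occurred in the gene name table used here. Genes are therefore described by abundance and by direction, and 4 are given by identifier.

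A group of 15 genes, each with a mean of at least 1000 TPM over the 6 libraries, accounted for most of the signal in every library. Whether they are mitochondrial transcripts could not be checked without gene names, so what a change of their share stands for is not known. Together they held 90.8% ± 2.42 of TPM in young ventricle and 94.3% ± 0.506 in old ventricle (mean ± SD, n = 3). The most abundant of them alone held 17.0% ± 1.64 in young and 17.2% ± 0.150 in old (n = 3). All other genes shared the remaining 9.19% ± 2.42 in young and 5.66% ± 0.506 in old, a level 1.62-fold higher in young. The 3 young values were 6.39%, 10.6% and 10.5%, and the 3 old values were 5.84%, 6.05% and 5.08%. The groups did not overlap, and the exact two-sided permutation test gave p = 0.1, the smallest value that 3 against 3 libraries allow. Young replicate 1 lay 0.345 percentage points above the highest old library on this measure.

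**Figure D1:**
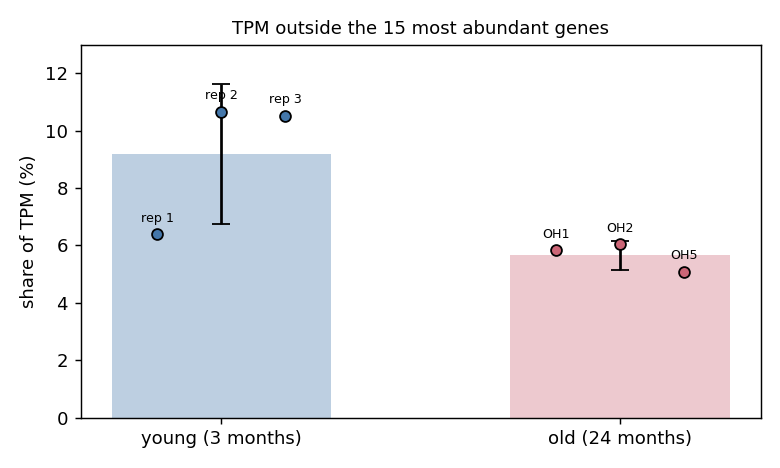
Share of TPM (percent, from 0) held by all genes other than the 15 most abundant, for young and old ventricle. Bars give the group mean, error bars the SD (n = 3) and points the libraries; the 3 old libraries lie between 5.08% and 6.05%, with young replicate 1 at 6.39% and the other young libraries at 10.6% and 10.5%.

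Within this group of 15 genes, 1 fell in old ventricle and 14 did not pass the threshold (limma-trend, Benjamini-Hochberg adjusted p below 0.05 over all 9502 tested genes). The gene that fell was the 13th most abundant, at 10512 ± 1627 TPM in young and 6108 ± 1307 TPM in old (SD, n = 3), a log2 fold change of -0.79 ± 0.24 (SE) with a limma adjusted p of 0.011. The eighth most abundant gene was at 48956 ± 6545 TPM in young and 63080 ± 3505 TPM in old, with a log2 fold change of 0.37 ± 0.16 and a limma adjusted p of 0.0514. The SE and adjusted p values of this fit rest mostly on a spread shared across all tested genes. They rest little on the libraries of a single gene, so the 14 genes that missed the threshold are not shown to be unchanged. As parts of the sum of the 15 genes, 4 had young and old libraries that did not overlap, 2 of them higher in old and 2 lower. Averaged over all splits of 3 against 3 libraries, 10% of genes do not overlap, and genes that vary together can depart from this in a single split. The 13th gene made up 1.16% ± 0.206 of that sum in young and 0.647% ± 0.135 in old (n = 3). The third most abundant gene made up 11.4% ± 1.11 in young and 9.40% ± 0.265 in old.

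The comparison of old with young ventricle across single genes depended on how the libraries were scaled. With TPM as deposited, 4533 of 9502 tested genes passed the threshold, 84 higher and 4449 lower in old (limma-trend on log2(TPM + 1), adjusted p below 0.05). The median log2 fold change of all tested genes was -0.53, and 5228 genes (55.0%) had groups that did not overlap. With the 15 abundant genes left out and the other genes rescaled to 1000000 per library, 576 of 9487 genes passed, 252 higher and 324 lower. The median log2 fold change was then -0.04, and 2818 genes (29.7%) had groups that did not overlap. Averaged over all splits of 3 against 3 libraries, 10% of genes do so. Genes share differences between libraries, so a single split can lie far from 10% without an effect of age. The percentages for the other splits are not given here. The share of calls that were higher in old was thus 1.85% on the deposited scale and 43.8% after rescaling, 51.2% with median-ratio scaling and 46.1% with quantile normalization. Each of these scalings brings the median change close to 0. Leaving out OH2 from the rescaled comparison raised the share to 68.5%. The column names end in _1 or _2 with no stated meaning, and this suffix as a second term of the model gave 1385 calls on the deposited scale (41 higher, 1344 lower) and 174 after rescaling (109 higher, 65 lower; 62.6% higher). The rescaling was chosen after the data were seen. Without the filter on low values 1 of 23976 genes passed on the deposited scale and 6 of 23961 after rescaling. At an unadjusted limma p below 0.05 were 6462 and 3437 genes. These fits include 5835 genes listed at 0 in all 6 libraries, which have no spread. They do not measure the effect of the filter on the other genes alone. Leaving out single libraries moved the deposited-scale count between 388 (without OH5) and 8857 (without young replicate 1). The rescaled count lay between 67 (without OH1) and 453 (without young replicate 1).

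**Figure D2:**
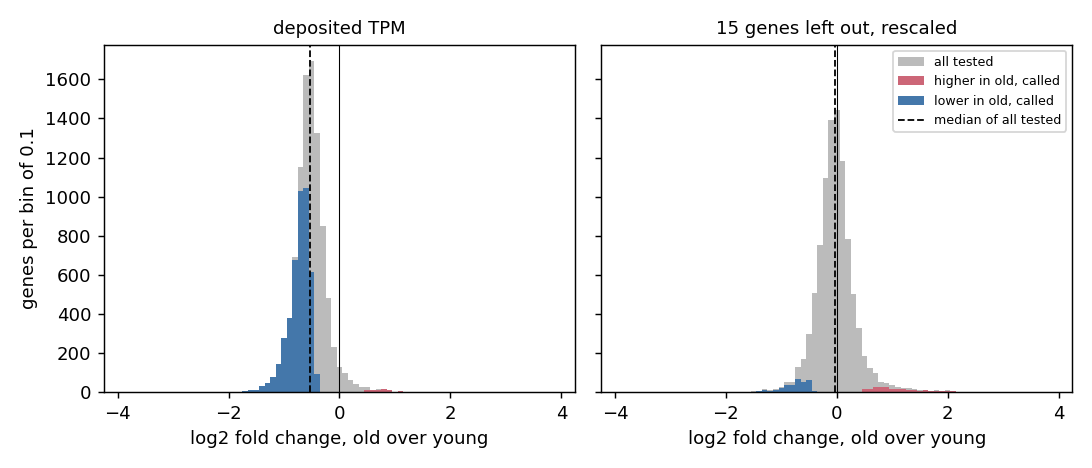
Number of tested genes (vertical axis, bins of 0.1) by log2 fold change of old over young (horizontal axis), on the deposited TPM scale and with the 15 most abundant genes left out. Gray bars give all tested genes, colored bars those past an adjusted p of 0.05, and the dashed line the median, which lies at -0.53 on the deposited scale and at -0.04 after rescaling.

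Rescaling raised the log2 fold change of 99.4% of the 9487 genes tested on both scales, by a median of 0.53, so a gene that falls after it is expected to fall on the deposited scale as well. This held for all 324 genes that fell after rescaling. Of the 252 genes that rose after rescaling, 68 had also risen on the deposited scale and 184 had not passed the threshold there. Of the 9487 genes, 392 passed on both scales in one direction, and 4140 passed on the deposited scale alone. After rescaling, the median log2 fold change was 0.99 among the genes that rose and -0.70 among those that fell. A change of at least 2-fold was reached by 125 of the genes that rose and 50 of those that fell.

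Among genes with a mean below 3 TPM, 129 rose and 83 fell after rescaling, out of 3963 tested. Among genes of 3 to 10 TPM, 90 rose and 158 fell, out of 4012 tested. Of the 1210 genes of 10 to 30 TPM, 28 rose and 74 fell, and of the 302 genes between 30 and 1000 TPM, 5 rose and 9 fell. On the deposited scale the corresponding numbers were 49 higher and 1797 lower below 3 TPM, and 24 higher and 1979 lower from 3 to 10 TPM. The odds that a rescaled call was higher in old were 3.04 times as large below 3 TPM as above it (95% interval 2.11 to 4.39, Fisher's exact test, two-sided, p = 3.00e-10). This test runs across genes, which are not independent replicates. Without OH2 the odds ratio was 1.57 (0.912 to 2.73).

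The gene with the largest rise among those past the threshold was ENSRNOG00000043451, at 0.677 ± 0.187 TPM in young and 5.91 ± 1.92 TPM in old (SD, n = 3). Its log2 fold change was 2.01 ± 0.22 (SE) on the deposited scale and 3.59 ± 0.38 after rescaling, with limma adjusted p values of 6.22e-11 and 0.00562. The pseudocount of 1 TPM makes the deposited-scale value an understatement for a gene at this level, as for any gene near 1 TPM in one group. The prior degrees of freedom of limma, the weight of the spread shared across genes, were 91.8 on the deposited scale and 4.22 after rescaling. Deposited-scale SE and adjusted p values therefore rest mostly on that shared spread and little on a gene's own libraries. ENSRNOG00000070397 rose from 1.51 ± 0.601 to 8.52 ± 2.77 TPM, a log2 fold change of 1.91 ± 0.25 on the deposited scale and 3.11 ± 0.28 after rescaling (limma adjusted p 1.92e-08 and 0.00527). ENSRNOG00000055972 fell from 11.6 ± 9.08 to 0.220 ± 0.105 TPM, a log2 fold change of -2.89 ± 0.29 on the deposited scale and -4.15 ± 0.95 after rescaling (limma adjusted p 2.17e-12 and 0.043). Its young libraries were uneven, at 18.5, 15.1 and 1.36 TPM, and after rescaling its limma adjusted p was 0.0694 with a pseudocount of 10, 0.0545 with median-ratio scaling and 0.1005 with the column suffix as a term (log2 fold change -4.21). With the 15 abundant genes kept, median-ratio scaling gave 0.0932 and quantile normalization 0.0916. With a pseudocount of 0.1, its deposited-scale log2 fold change was -4.59. The unevenness of its young libraries hardly enters the deposited-scale SE of 0.29 and limma adjusted p of 2.17e-12. ENSRNOG00000023465 fell from 43.6 ± 14.4 to 8.62 ± 4.46 TPM, a log2 fold change of -2.30 ± 0.33 on the deposited scale and -1.79 ± 0.36 after rescaling (limma adjusted p 4.16e-07 and 0.0291; with the suffix as a term after rescaling, -1.64 and 0.0764). When single libraries were left out of the rescaled comparison, both genes that rose passed the threshold in all 6 fits. ENSRNOG00000055972 missed it in 5 of 6 fits (limma adjusted p 0.00300 to 0.122 over the 6) and ENSRNOG00000023465 in 4 of 6 (0.0243 to 0.0883). The log2 fold change of the former ran from -5.44 (without young replicate 3) to -3.25 (without young replicate 1). That of the latter ran from -2.07 (without OH1) to -1.31 (without OH5). Without the filter on low values none of the 4 genes passed on either scale, at the same fold changes. Those fits include the 5835 genes without spread named above. The limma adjusted p on the deposited scale and after rescaling was 0.0553 and 0.0950 for ENSRNOG00000043451 and 0.0628 and 0.0824 for ENSRNOG00000070397. It was 0.130 and 0.251 for ENSRNOG00000055972 and 0.0873 and 0.199 for ENSRNOG00000023465.

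Few genes were listed at 0 in one age group and detected in the other. Listed at 0 in all 3 old libraries and at 0.1 TPM or more in all 3 young libraries were 3 genes, and the reverse was found for 0 genes. At a minimum of 0.5 TPM the numbers were 2 and 0. A further 5835 genes were listed at 0 in all 6 libraries. The number of genes above 0 was 16141 ± 842 in young and 16121 ± 362 in old (SD, n = 3; exact two-sided permutation p = 0.9). The number at 1 TPM or more was 9967 ± 781 in young and 8704 ± 290 in old (exact two-sided permutation p = 0.1, the smallest possible), and 1 TPM stands for a different part of the non-abundant genes in each library.

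The young libraries differed from one another more than the old ones did on the deposited scale. The median SD of log2(TPM + 1) within a group was 0.342 in young and 0.135 in old. After rescaling these medians were 0.179 and 0.130. Pearson correlations of deposited log2 values across genes, which are not independent replicates, were 0.963 to 0.980 within young, 0.975 to 0.987 within old and 0.943 to 0.966 between ages. Among the young libraries, young replicate 1 had the lowest correlation with each old library. Its values were 0.943 to 0.949 on the deposited scale and 0.917 to 0.923 after rescaling. On the first principal component of the deposited values (81.8% of the variance), young replicate 1 lay at 7.51, between the other young libraries at -45.7 and -48.7 and the old libraries at 21.9 to 41.3. After rescaling, the first component (49.3%) placed the 3 young libraries at -26.5 to -13.8 and the 3 old libraries at 16.7 to 22.1. Young replicate 1 was then the young library farthest from the old ones, at -26.5, so its place between the ages was not kept. The second component (22.5%) then held young replicate 1 at 19.5 and OH5 at 14.6, apart from the other libraries of their ages.

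**Figure D3:**
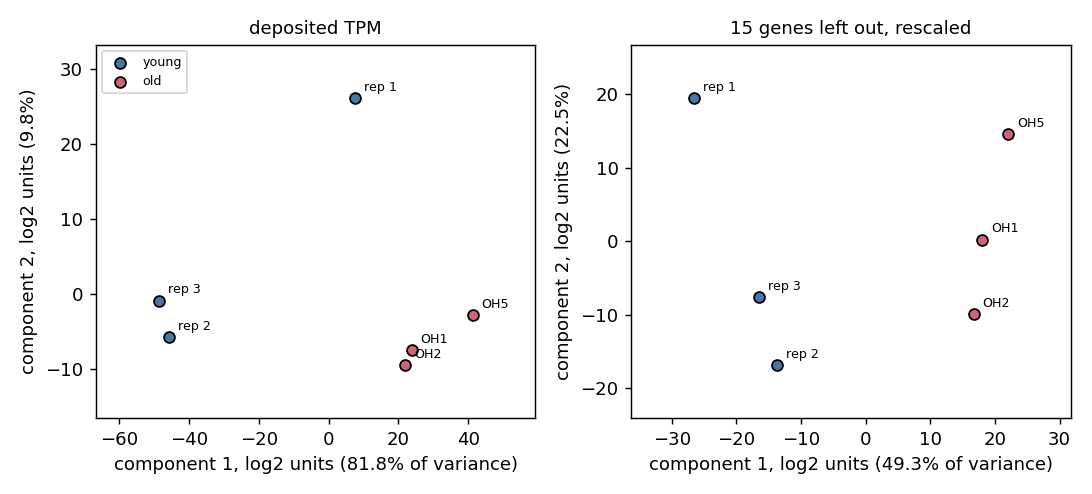
First and second principal components of log2 values of the tested genes for the 6 libraries, on the deposited TPM scale and with the 15 most abundant genes left out, with the share of variance on each axis. On the deposited scale young replicate 1 lies at 7.51 on component 1, between the other young libraries and the old ones. After rescaling, young and old libraries lie on opposite sides of 0, and young replicate 1, at -26.5, is the young library farthest from the old ones.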

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

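Scalings other than the deposited one, and every alternative to the rescaled comparison, were chosen after the data were seen. On the deposited scale (4533 genes, 84 higher and 4449 lower), a pseudocount of 0.1 changed the counts by less than 1.5 times. Without a filter on low values 1 gene passed, 0 higher and 1 lower, with 6462 genes at an unadjusted p below 0.05. The prior degrees of freedom of limma's test then fell from 91.8 to 0.841. Each fit without a filter held 5835 genes listed at 0 in all 6 libraries, which have no spread. Its count therefore does not measure the effect of the filter on the other genes alone. How far the genes without spread account for the fall was not tested. With the 15 abundant genes left out, 576 genes passed, 252 higher and 324 lower. Median-ratio scaling gave 553 (283 higher, 270 lower) and quantile normalization 577 (266 higher, 311 lower). Leaving out one library on the deposited scale gave 388 to 8857 genes, 29 to 73 higher and 359 to 8784 lower. The highest count came without young replicate 1. The old minus young gap in the share outside the 15 genes was then -4.93 percentage points, against -3.53 with all libraries. The median log2 fold change was -0.72 against -0.53. No further test of the cause was run. In the rescaled comparison, pseudocounts of 0.1 and 10, a filter at 10 rescaled TPM, a lower bound of 100 TPM for the genes left out and median-ratio scaling kept the counts within 1.5 times. No filter gave 6 genes, 2 higher and 4 lower, with 3437 at an unadjusted p below 0.05. Leaving out one library gave 67 to 453 genes, 36 to 196 higher and 31 to 259 lower, and fewer libraries enter these fits. The suffix of the column names as a second term, with fewer residual degrees of freedom, gave 1385 genes (41 higher, 1344 lower) on the deposited scale and 174 (109 higher, 65 lower) in the rescaled comparison. What the suffix means is not known. The deposited-scale fit with this term, and those without young replicate 2, OH1, OH2 or OH5, had infinite prior degrees of freedom. Their tests used only the spread shared across genes. Without young replicate 1 the value was 9.19. The deposited-scale counts therefore differ in how far a gene's own spread entered the test. Over 100 alternative values of the 4 named genes, 77 kept direction and side of the threshold, 23 kept direction but missed it, and 0 reversed. The genes were picked for large changes and groups that did not overlap. Leaving out a library could thus not reverse them, and the absence of reversals is no evidence of stability. No paired analysis was possible because the numbers in the old column names do not match the old samples' labels, so no old column could be given a replicate number. The depth of the libraries is unknown, so what depth limits cannot be stated.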

Other observations

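The 14th and 15th most abundant genes moved together. They stood at 21867 and 17604 TPM in young replicate 2 and at 3020 and 2428 TPM in young replicate 1, a 7.24-fold range for the former over the 6 libraries. Their ratio stayed between 1.14 and 1.25 in all 6 libraries. Neither passed the threshold between ages (limma adjusted p 0.259 and 0.255).

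The tests in the next paragraphs on the scale of the calls, on regrouping and on the labelling of young replicate 1 were chosen only after the results were seen.

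On the deposited scale 98.1% of the genes past the threshold were lower in old ventricle. The effect of a single library was tested by leaving each out, and the share of higher calls stayed between 0.824% and 9.39%. This argues against a single library as the sole cause. Every such fit kept young replicate 2 or 3, which had 10.6% and 10.5% of TPM outside the 15 genes. The fits therefore cannot tell whether these libraries together carry the direction. The closed sum of TPM, in which a larger share of the 15 abundant genes lowers every other value, stays open as an explanation. After these genes were left out, 43.8% of calls were higher (68.5% without OH2), but the rescaling centres the fold changes and would also remove a real common fall, so this decides nothing. Simulated libraries given the real shares and no other change had 271 calls among 9487 genes, against 4533 among 9502 in the real libraries. Genes with an unadjusted limma p below 0.05 numbered 5407 against 5979, and the median log2 fold change was -0.51 against -0.53. The simulation was a single draw with noise drawn separately for each gene. The gap between the call counts therefore does not measure the part of the calls due to the shares. Whether the share itself changes with age also stays open, since the exact permutation p of 0.1 is the smallest that 3 against 3 libraries allow, and a difference in RNA extraction or depletion cannot be told apart from age here.

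The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. On the deposited scale the real split gave 4533 calls and the highest of the others 10, so that 1 split reached the real count. After rescaling the real split gave 576 calls and the highest of the others 1, and again 1 split reached the real count.

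Young replicate 1 stood apart from the other young libraries. A mislabelled sample would lie with the old libraries, but over 453 genes called without it after rescaling, its median position was 0.803 on a scale from the old mean at 0 to the mean of the other young libraries at 1 (quartiles 0.593 and 1.07). Its larger share of the abundant genes stays open as an explanation for part of the gap: it was the odd one of the 3 young libraries for 82.7% of genes on the deposited scale and for 44.9% after rescaling, against 29.5% and 25.6% for the others. The 44.9% lies between the bounds set for a full and for no explanation (40% and 45%), and rescaling also centres each library, so the test decides nothing. No biological explanation was tested, because the labels give no difference between the young animals.

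After rescaling, calls higher in old lay at lower expression than calls lower in old, a hypothesis drawn from these data. A pseudocount of 10 in place of 1 left the odds ratio at 2.85 (95% interval 1.98 to 4.12). Genes split at the median of their rescaled level, in place of the deposited mean, gave 3.01 (2.11 to 4.31). The odds ratio of the main comparison was 3.04, so these values argue against the pseudocount and the scale of the level as sources of the pattern. The intervals run across genes, which are not independent replicates, and do not measure the spread between animals. The genes were still filtered on deposited TPM, and an effect of that filter was not tested. A single library could still carry it: over the leave-one-out fits the odds ratio lay between 1.57 and 4.50, and without OH2 its interval of 0.912 to 2.73 included 1. Transcript length and a change in cell composition with age were not tested, since neither lengths nor gene names were used here.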
